A study of Mus musculus with 2 samples.

How the data were processed

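H3K27me3, the trimethylation of lysine 27 of histone H3 that is laid down by Polycomb repressive complex 2 and goes with gene silencing, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole hearts of mouse embryos of the B6NCrl strain at embryonic day 16.5. There were 2 biological replicates of mixed sex, each from 2 technical replicates, per the labels. Replicate 2 pooled the hearts of 41 embryos, per the labels, and the number of embryos for replicate 1 was not given in the sources used here. The labels name them as separate biological replicates. All samples fell into one group, so the design held no contrast between conditions. Comparisons were made between the replicates, between gene lists and other genes, and between places in the genome.

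The deposited files were 4 narrowPeak lists on the mm10 build, per the labels. There was 1 list for each replicate, 1 called on both replicates together and 1 of replicated peaks. The replicated list was derived from the list of both replicates together and the 2 replicate lists, per the deposited descriptions, which do not give the rule. The list of replicate 1 was derived from its alignments and 2 further files, and that of replicate 2 from its alignments and 1 further file, whose roles are not described there. The aligner, the peak caller, their versions and the filters are not given in the sources used here. A control library is named as possible in the labels and was not analysed here. Each deposited peak carries a display score, an enrichment signal and the −log10 of a p-value and of a q-value, all as the authors' caller gave them. These values were used only to describe, rank or filter peaks within a list. No peak had a −log10 p under 2.00. Read counts were not used here, so the depth of each library is unknown, and a peak is a presence call: a place without a peak can hold the mark below the caller's limit. Calls on each replicate's own data and calls on pooled data were kept apart for that reason.

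Genes came from the GENCODE annotation (release M21) of GRCm38, the assembly that mm10 names, with sequence from RefSeq's GRCm38 assembly. All peaks lay within its chromosome ends, on 19 autosomes and chromosome X. The annotation gave 21728 protein-coding genes with distinct symbols, and all 426 symbols of the 18 gene lists were found in it. The gene start was the outermost 5′ end of the gene record, so a gene with several promoters was represented by one of them. A gene was called marked when at least 1 base within 1 kb either side of its start lay in a peak. Shares of list members carry exact (Clopper-Pearson) 95% binomial intervals, which treat members as independent draws. The main list was the replicated list, with each replicate's own list beside it. Counts of marked list members given for a replicate alone come from its own list and include genes that the other replicate also marked.

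The 18 lists were tested with two-sided Fisher's exact tests against all other protein-coding genes, with Benjamini-Hochberg adjustment over the lists. Families of genes that share the letters of the symbol before the first digit, with 8 or more genes, were tested in the same way. The overlap of the replicates and the place of the mark were set against 100 random placements of the peaks on the same chromosomes, outside assembly gaps and without overlap within the list. The smallest one-sided p they can give is 0.0099 and the smallest two-sided p 0.0198. Genomic place was assigned in the order promoter (the 1 kb windows), exon, intron and intergenic. Peaks of the replicated list less than or exactly 3 kb apart were merged into domains. Promoter CpG content was the observed over expected CpG ratio of the window, and a ratio of 0.6 or more was called CpG-rich.

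The genes named were chosen by a rule written before the data were examined. It took, from each list, the 4 marked members with most bases covered within 5 kb either side of the gene start, and up to 4 members that went against the majority. It added the genes that start in the 10 widest domains and the 10 families with the smallest p. It also added the 5 genes per replicate with most coverage among those marked in that replicate and not in the other. Other members of a list are named to complete its description and were chosen after their values were seen. Alternatives fixed beforehand were a −log10 q of at least 2, each replicate alone, the list of both replicates together, windows of 500 and 2500 bases, 50% of the window or of the peak covered, 10000 random gene sets matched on promoter CpG content in 20 bins, members within 100 kb of each other counted once, equal numbers of peaks, and merging gaps of 1 and 10 kb. After seeing the data, the peaks of the list of both replicates together that overlap both replicate lists were added, and for list members in domains of at least 10 kb, each replicate alone and neighbours counted once.

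The list test was checked on simulated data: in 50 simulations over the 21728 genes with a 3-fold higher share of marked genes in some lists, 71.7% of these lists were called, the median fold recovered was 2.97 and 0.5% of unaltered lists were called. The simulations marked each gene independently, so these rates do not hold for lists or families whose members are neighbours that share the mark. Computations used Python 3.11.15, bedtools 2.31.1, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.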

Results

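H3K27me3 was mapped in whole hearts of mouse embryos at embryonic day 16.5, in 2 biological replicates of mixed sex. The heart at this stage holds cardiomyocytes, endothelial and endocardial cells, fibroblasts, epicardium, smooth muscle and blood, and the peaks come from all of them together. The replicated list held 35396 peaks, which covered 23.4 Mb or 0.916% of the genome. Replicate 1 had 80950 peaks over 34.2 Mb and replicate 2 had 33344 peaks over 12.7 Mb. The depth of each library is unknown, because the peak lists give no read counts. With one tissue, one stage and one antibody, the data show where the mark lay, and no change between conditions was tested.

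By the authors' p, the first peak of the replicated list covered the start of Dio3, the deiodinase that inactivates thyroid hormone, over 7725 bases on chromosome 12. The next were 1896 bases from the start of Ptf1a, a pancreatic and hindbrain transcription factor, and over the start of Neurog3, which drives endocrine cell fate in the pancreas. Barhl1, a neural homeobox gene, and Kcnk9, a potassium channel gene, followed. Dio3 and Ptf1a were also nearest to peaks among the 10 strongest of each replicate. The first peak of replicate 1 lay at Neurog3 and that of replicate 2 lay 5474 bases from the start of Neurod2, a neuronal transcription factor. These peaks were named after their values were seen.

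Of 21728 protein-coding genes, 3089 (14.2%) had the mark within 1 kb of the gene start in the replicated list. Replicate 1 marked 4013 genes (18.5%) and replicate 2 marked 2610 (12.0%), with 2479 genes marked in both. Thus 2479 of the 2610 genes marked in replicate 2 were also marked in replicate 1, and 61.8% of those of replicate 1 in replicate 2. Among the 1534 genes marked in replicate 1 and not in replicate 2, those with most coverage were Dbn1, Osr2, Zfp536, Hlx and Tbx2. Dbn1 encodes the actin-binding protein drebrin, and Osr2, Hlx and Tbx2 are developmental transcription factors. In the 10 kb around the start of Dbn1, peaks covered 7.34 kb in replicate 1 and 2.71 kb in replicate 2. Around Osr2, Zfp536, Hlx and Tbx2, replicate 2 peaks covered 1.54 to 3.17 kb. For each of these genes the replicate 2 peaks lay outside the 1 kb window. Another 131 genes were marked in replicate 2 and not in replicate 1, led by Apc2, Zfp423, Aspdh, Fam222a and Psmb9. Around Apc2 the coverage was 3.11 kb in replicate 2 and 3.55 kb in replicate 1, so that the peaks of replicate 1 lay nearby and outside the 1 kb window.

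Among the 18 lists, transcription factor genes that set the identity of other tissues had the largest shares of marked members. This held in the replicated list and in each replicate. With peaks of both replicates together, neurotransmission and neuronal genes (85.7%) stood above the factors of endoderm, kidney, gonad and epidermis (83.3%). All 39 Hox genes, which pattern the body axis, were marked in the replicated list and in each replicate (95% exact interval 91.0% to 100% of members). Against 14.1% of other genes this was 7.11-fold more often (two-sided Fisher's exact test, adjusted exact p = 1.3e-32). Of the 10 kb around the gene start, peaks covered 9.86 kb at Hoxd11, 9.86 kb at Hoxc12, 9.77 kb at Hoxb13 and 9.71 kb at Hoxa3. All 38 neural fate transcription factors were marked as well (7.11-fold, adjusted exact p = 4.7e-32), again in both replicates. Coverage reached 9.96 kb at Olig2, which specifies oligodendrocytes and motor neurons, 9.96 kb at Six3, a forebrain and eye regulator, 9.94 kb at Neurog1 and 9.72 kb at Pax6. Of the 24 transcription factors of endoderm, kidney, gonad and epidermis, 20 were marked (5.89-fold, adjusted exact p = 2.9e-13), with 21 in replicate 1 and 20 in replicate 2. The intestinal factor Cdx2 had 9.92 kb covered, the liver and pancreas factor Onecut1 9.86 kb, Pax9 9.45 kb and the mesoderm factor T, or brachyury, 9.39 kb. The 4 unmarked members were Hnf1a, Hnf4a, Foxn1 and Trp63. Genes of one Hox cluster are neighbours and not independent, and members within 100 kb of each other were therefore also counted once. This left 4 Hox and 35 neural units, all of them marked. Both lists stayed past the threshold (adjusted exact p = 0.00088 and 3.3e-29).

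Of the 39 Wnt, FGF and hedgehog ligand genes, 30 were marked (5.45-fold, adjusted exact p = 1.2e-17), with 31 in replicate 1 and 26 in replicate 2. Wnt10a had 9.86 kb of 10 kb covered, Shh 9.73 kb, Wnt3 8.96 kb and Wnt7a 8.86 kb. Among the 9 unmarked ligands were Fgf1, Fgf10, Fgf20 and Fgf23, none of which had a covered base within 5 kb in either replicate. Of 21 genes of neurotransmission and neuronal function, 17 were marked (5.72-fold, adjusted exact p = 4.6e-11), 18 in replicate 1 and 15 in replicate 2. These included the glycine transporter Slc6a5 with 9.74 kb covered, the vesicular inhibitory amino acid transporter Slc32a1 with 9.40 kb, the GABA-synthesising enzyme Gad2 with 9.06 kb and the neurofilament gene Nefl with 7.46 kb. Gad1, Gria1, Scn1a and Syn1 were unmarked. Of 14 neural crest, glial and autonomic genes, 8 were marked (4.03-fold, adjusted exact p = 0.00050), among them the receptor Ret with 8.11 kb, the neural crest factor Foxd3 with 7.82 kb, Prph with 6.98 kb and Sox10 with 6.26 kb. Dbh, Ednrb, Elavl4 and Mpz were unmarked members, and replicate 1 marked 11 genes of this list against 8 in replicate 2.

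Cardiac transcription factors were split. Of 27, 14 were marked, 3.66-fold more often than other genes (adjusted exact p = 1.3e-05), with 15 in replicate 1 and 12 in replicate 2. The largest coverage was 7.58 kb at Isl1, a factor of second heart field progenitors, 7.52 kb at Pitx2, which sets left-right asymmetry, 7.26 kb at Tbx1, a factor of pharyngeal and outflow tract progenitors, and 6.87 kb at Tbx3, a factor of the conduction system. In the same order, coverage was 8.05, 7.20, 7.47 and 6.65 kb in replicate 1 alone and 4.43, 3.32, 5.19 and 4.49 kb in replicate 2 alone. Hand1, Gata5, Tbx20, Shox2, Irx3, Irx4, Irx5 and Esrrg were also marked, while Nkx2-5 and Tbx2 were marked in replicate 1 and not in replicate 2. In the 10 kb around the start of Tbx2, replicate 2 peaks covered 2.98 kb, all outside the 1 kb window. Gata4 and Gata6, zinc finger factors of the myocardium, had 0 and 0.185 kb covered, Hand2 0.235 kb and Ankrd1 0. Tbx5, Mef2a, Mef2c, Mef2d, Srf and Myocd were unmarked too. The list thus counts cofactors such as Ankrd1 and Myocd with the transcription factors.

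For the contractile and metabolic genes of cardiomyocytes, no difference from other genes passed the test. Of 33 contractile and conduction genes, 4 were marked (12.1%, exact interval 3.40% to 28.2%), a 0.852-fold share with an adjusted exact p of 1. Of the myosin, troponin, actin and titin genes of the list, including Myh6, Myh7, Tnnt2, Actc1 and Ttn, none was marked in the replicated list. The 4 marked members were the sodium channel Scn5a with 4.82 kb covered, the nebulin-related Nebl with 1.67 kb, the potassium channel Kcnq1 with 1.65 kb and the calcium release channel Ryr2 with 1.37 kb, all marked in both replicates. In the same order, coverage was 5.345, 2.111, 2.529 and 1.961 kb in replicate 1 alone. It was 2.445, 0.369, 0.563 and 0.613 kb in replicate 2 alone. The list of replicate 1 by itself marked 8 of the 33 (24.2%), the further ones being Myl2, Myl7, Actn2 and Myom2. The direction of this list changed between settings, with 1.01-fold in replicate 2 alone and 1.31-fold in replicate 1 alone. Of 15 genes of cardiac energy metabolism, 1 was marked (0.469-fold, adjusted exact p = 0.912). It was the muscle creatine kinase gene Ckm, with 3.03 kb covered, and replicate 1 alone marked 2 (0.722-fold), with Fabp3.

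The lists of fibroblast and of endothelial genes were marked more often than other genes. Of 18 fibroblast, epicardial and valve genes, 11 were marked (4.31-fold, adjusted exact p = 1.5e-05), with 11 in replicate 1 and 10 in replicate 2. The epicardial factor Wt1 had 7.54 kb covered, Twist1 7.45 kb, Bnc1 7.34 kb and Sox9 6.52 kb. In the same order, coverage was 7.39, 7.34, 7.64 and 6.47 kb in replicate 1 alone and 3.93, 3.73, 5.05 and 4.21 kb in replicate 2 alone. The matrix genes Col3a1, Dcn, Dpt and Lum had no covered base within 5 kb in either replicate, whereas Col1a1 and Col1a2 were marked. Of 18 endothelial and endocardial genes, 8 were marked (3.13-fold, adjusted exact p = 0.0038), with 11 in replicate 1 and 7 in replicate 2. They included the factors Sox17 with 6.28 kb, Sox18 with 4.61 kb and Erg with 3.91 kb, and the VEGF receptor Flt1 with 5.27 kb, while Pecam1, Cdh5, Kdr and Tek were unmarked. Of 13 smooth muscle and pericyte genes, 4 were marked (2.17-fold, adjusted exact p = 0.165). Replicate 1 alone marked 6 of them (2.50-fold, adjusted exact p = 0.034) and replicate 2 alone marked 2 (1.28-fold, adjusted exact p = 0.990). The 4 were the smooth muscle myosin Myh11 with 4.71 kb, Mylk with 1.58 kb, Pdgfrb with 1.28 kb and Des with 0.733 kb, of which Myh11 and Pdgfrb were not marked in replicate 2. Across the fibroblast, endothelial and smooth muscle lists, all 11 transcription factors were marked. Of the other 38 genes 12 were marked (31.6%), with 17 in replicate 1 alone and 11 in replicate 2 alone. The single lists were not tested without these factors.

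For 6 other lists no difference from other genes passed the test. Of 21 skeletal muscle genes, 5 were marked (1.68-fold, adjusted exact p = 0.312). All 5 were transcription factors, namely Pax7 with 9.94 kb covered, Pax3 with 8.01 kb, Lbx1 with 7.67 kb, Myod1 with 5.76 kb and Six1. The muscle transcription factors Myf5, Myf6 and Myog were unmarked, as were the skeletal myosin genes. With 50% of the window required to be covered, this list passed the threshold (3.19-fold, adjusted exact p = 0.031). Of 22 blood and immune genes, 3 were marked (0.959-fold, adjusted exact p = 1): the B cell factor Pax5 with 8.37 kb, the complement gene C1qa with 4.60 kb and the erythropoietin receptor Epor with 2.61 kb, with 5 marked in replicate 1 and 2 in replicate 2. Of 19 liver, pancreas and gut genes, only Apoa1 and Muc2 were marked (0.740-fold, adjusted exact p = 1). Of 18 germline and pluripotency genes, 3 were marked (1.17-fold, adjusted exact p = 0.912), namely Pou5f1 with 3.22 kb, Nanog with 0.503 kb and Tdrd1 with 0.436 kb. Replicate 1 alone marked 3 (0.902-fold) and replicate 2 alone 1 (0.462-fold). Of the 22 genes for Polycomb proteins and H3K27 demethylases, Cbx8 with 5.20 kb and Pcgf1 with 3.94 kb were marked (0.639-fold, adjusted exact p = 0.912), and in replicate 1 alone 4 (0.984-fold), with Cbx2 and Cbx4. None of 25 housekeeping genes was marked in any of the replicated list and the 2 replicate lists (exact interval 0% to 13.7%; adjusted exact p = 0.073). Housekeeping genes passed the threshold in replicate 1 alone (adjusted exact p = 0.016) and not in replicate 2 alone (adjusted exact p = 0.106).

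In all, 9 of 18 lists were marked more often than other genes and 0 less often by Fisher's exact test after adjustment. At an unadjusted p under 0.05, 9 lists were more often and 1 list, the housekeeping genes, less often marked. The 9 lists also passed against gene sets matched on promoter CpG content, with adjusted p from 0.00051 to 0.0116, and CpG-rich gene starts as a whole were marked in 15.6% of cases against 13.5% of CpG-poor ones, with 18.6% against 18.4% in replicate 1 and 14.00% against 10.98% in replicate 2.

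**Figure D1:**
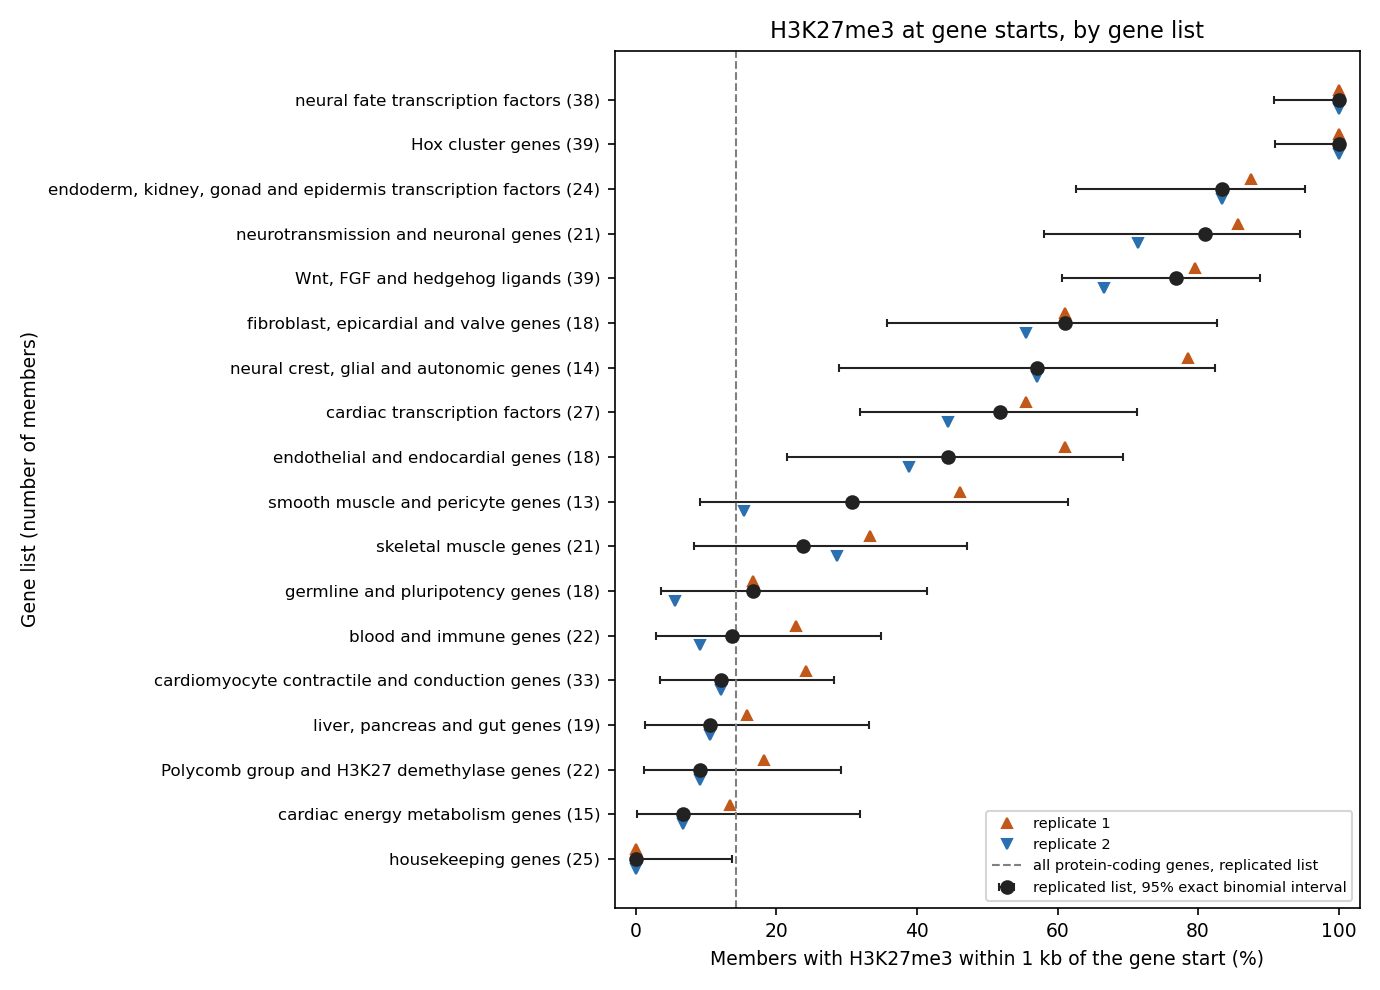
Percent of members of each of the 18 gene lists with an H3K27me3 peak within 1 kb of the gene start (x axis, number of members in parentheses on the y axis): black points with 95% exact binomial intervals are the replicated list, orange and blue triangles replicates 1 and 2, and the dashed line is the 14.2% of all protein-coding genes. Hox and neural fate genes lie at 100% in the replicated list and both replicates, and housekeeping genes at 0%.

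Gene families were also formed by symbol alone, without a choice of members. Of 359 families, 38 were marked more often and 12 less often than other genes (Fisher's exact test, adjusted over the families). Against sets matched on promoter CpG content, 32 of the 38 and 9 of the 12 also passed, and without replicate 1 the families marked less often numbered 7. Of the 10 with the smallest p, 3 were marked less often: 4 of 1134 olfactory receptor genes (Olfr, 0.0235-fold, adjusted exact p = 7.1e-68), 53 of 1341 predicted genes with the provisional Gm symbol (0.265-fold, adjusted exact p = 1.0e-34) and 0 of 330 vomeronasal receptor genes (Vmn, adjusted exact p = 1.5e-20). Much of these deficits went with CpG content: in CpG-matched sets 2.74%, 9.26% and 2.25% of genes were marked, against 0.353%, 3.95% and 0% of the Olfr, Gm and Vmn genes (adjusted p = 0.0031, 0.0031 and 0.0144, permutation). The other 7 were marked more often. They were all 14 Nkx homeobox genes (7.06-fold, adjusted exact p = 1.2e-10), 16 of 19 Wnt genes (5.95-fold, adjusted exact p = 1.2e-09), 14 of 17 synaptotagmin genes (Syt, 5.81-fold, adjusted exact p = 3.1e-08) and the complete Hoxa, Hoxb, Hoxc and Hoxd sets of 11, 10, 9 and 9 genes. All 10 kept their direction and their side of the threshold in each replicate, where Nkx genes were marked in 14 and 12 cases and Syt genes in 14 and 11. Without replicate 2 the Olfr genes marked rose to 13 (0.0590-fold), the Gm genes to 93 (0.361-fold) and the Vmn genes to 1, and with peaks found in both replicates 1 Olfr gene was marked (0.0074-fold). Receptor genes of the Olfr and Vmn families lie in clusters, and the genes of each Hox family are neighbours in one cluster. The p-values of these families therefore overstate the number of independent genes, and neighbours were not counted once in the family tests.

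H3K27me3 was concentrated at gene starts. Promoters held 14.0% of the covered bases against 1.73% ± 0.085 (SD over 100 random placements), an 8.09-fold excess. Exons outside promoters held 12.2% (2.55-fold), introns 40.6% (0.948-fold) and intergenic space 33.2% (0.656-fold). Each p was 0.0198, the smallest two-sided value that 100 placements can give. The promoter excess was 6.07-fold in replicate 1 and 9.23-fold in replicate 2. The median GC content of replicated peaks was 50.4% against 41.6% for 500-base tiles of the genome. Chromosomes 11 and 19 had the largest covered share, 1.59% and 1.58%, and chromosome X the smallest, 0.404%. The same order held in replicate 1 alone (2.26%, 2.20% and 0.539%) and in replicate 2 alone (0.875%, 0.860% and 0.233%). In the replicated list, chromosome 15 had the largest share of marked genes, 169 of 784 (21.6%), of which 9 were Hoxc genes.

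Merging replicated peaks up to 3 kb apart gave 10956 domains, of which 853 spanned at least 10 kb, and 668 protein-coding genes started in these. Without replicate 2 there were 27572 domains, 1595 of at least 10 kb and 1075 such genes, and without replicate 1 9818, 572 and 464. The 4 widest were the 4 Hox clusters. The Hoxc domain spanned 241153 bases (chromosome 15, 102892843 to 103133995, mm10), with 134 peaks over 82.5% of its length, and held the starts of Hoxc4 to Hoxc13 and of the non-coding Hotair. The Hoxb1 to Hoxb9 domain spanned 149545 bases (chromosome 11, 96242444 to 96391988), the Hoxa domain 138654 bases (chromosome 6, 52143572 to 52282225) and the Hoxd domain with Evx2 123983 bases (chromosome 2, 74643360 to 74767342). All 39 Hox genes and 36 of 38 neural fate factors started in a domain of at least 10 kb, against 2.90% and 2.91% of the respective other genes (Fisher's exact test, adjusted exact p = 6.3e-59 and 8.5e-52). Of the cardiac transcription factors 11 of 27 did (adjusted exact p = 6.4e-10), and of the contractile and conduction genes 1 of 33 (adjusted exact p = 1). The domains did not follow the calls at gene starts in each list: of the endothelial genes 1 of 18 lay in them (1.81-fold, adjusted exact p = 0.688; 2 without replicate 1, 5.22-fold, p = 0.111, and 3 without replicate 2, 3.38-fold, p = 0.102), and of the skeletal muscle genes 4 of 21 (6.23-fold, adjusted exact p = 0.0079). Neighbours share a domain, and with members within 100 kb counted once, a setting chosen after seeing the data, 4 of 4 Hox and 33 of 35 neural fate units remained (adjusted exact p = 1.8e-06 and 5.0e-47).

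The next 6 domains lay outside the Hox clusters. Pax7, the factor of muscle stem cells, started in a domain of 81593 bases (chromosome 4, 139778874 to 139860466), and Tbx3 in one of 76440 bases (chromosome 5, 119617955 to 119694394). The other 4 held no protein-coding start. One of 102037 bases on chromosome 9 (61266495 to 61368531) held the start of the non-coding B930092H01Rik. A neighbouring one of 89241 bases (61374102 to 61463342) lay over Tle3, a transcriptional corepressor gene, without its start. One of 91636 bases on chromosome 7 (79493372 to 79585007) held Mir9-3hg, the host gene of microRNA miR-9-3. One of 77467 bases on chromosome 19 (44623965 to 44701431) held the non-coding Gm26644. Replicate 1 peaks covered 65.8% to 89.8% of each of the 10 domains and replicate 2 peaks 33.6% to 68.0%.

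**Figure D2:**
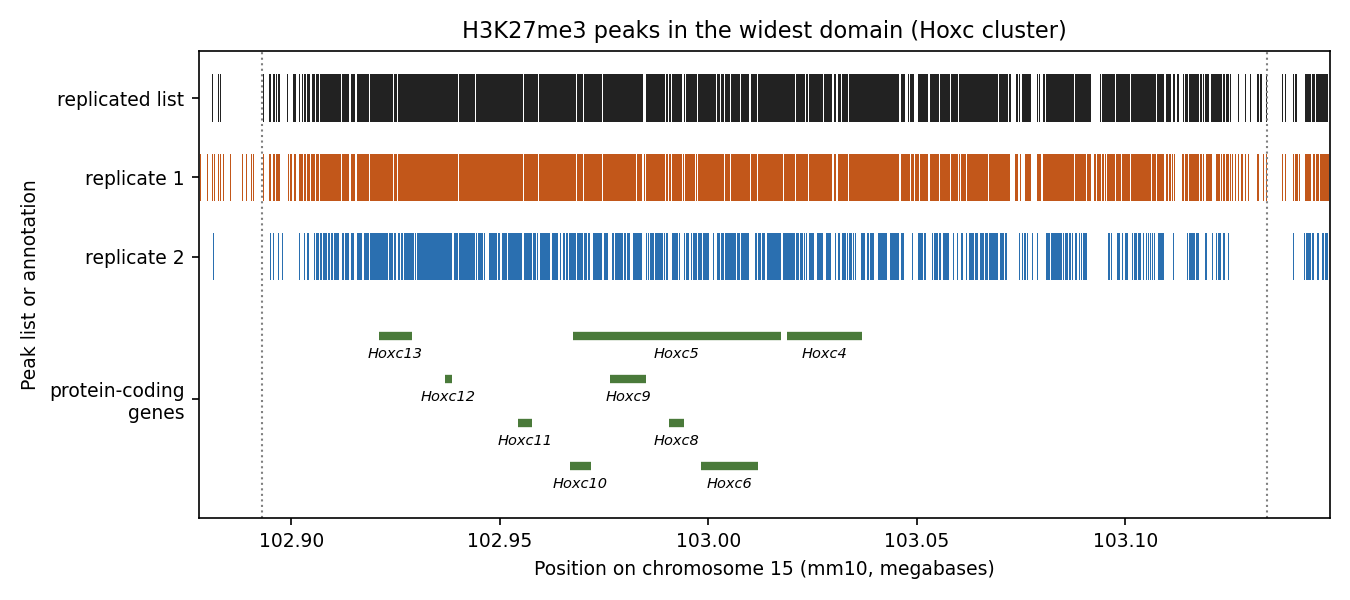
Peaks of the replicated list (black), replicate 1 (orange) and replicate 2 (blue) along the Hoxc region of chromosome 15 (x axis, mm10 position in megabases), with protein-coding gene records in green and dotted lines at the ends of the 241153-base domain. Peaks cover 83.8% of the domain in replicate 1 and 57.2% in replicate 2.

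Replicate 1 had 2.43 times the peaks of replicate 2 and 2.69 times the covered bases. Of the replicate 2 peaks, 80.3% (26772 of 33344) overlapped a replicate 1 peak, against 2.51% ± 0.088 (SD) for 100 random placements. Of the replicate 1 peaks, 24.4% (19772 of 80950) overlapped replicate 2, against 0.981% ± 0.036 (SD). Both lay above all 100 placements (permutation p = 0.0099, one-sided, the smallest they can give). The Jaccard index of the covered bases was 0.276. Of the strongest 10% of replicate 1 peaks by the authors' p, 84.2% overlapped replicate 2, and of the weakest 10%, 7.78%. Replicate 1 peaks found in replicate 2 had a median −log10 p of 7.42 and a median width of 539 bases, and those not found 4.48 and 235 bases. When both lists were held to the 33344 strongest peaks, 43.9% of replicate 1 peaks and 67.0% of replicate 2 peaks were shared.

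**Figure D3:**
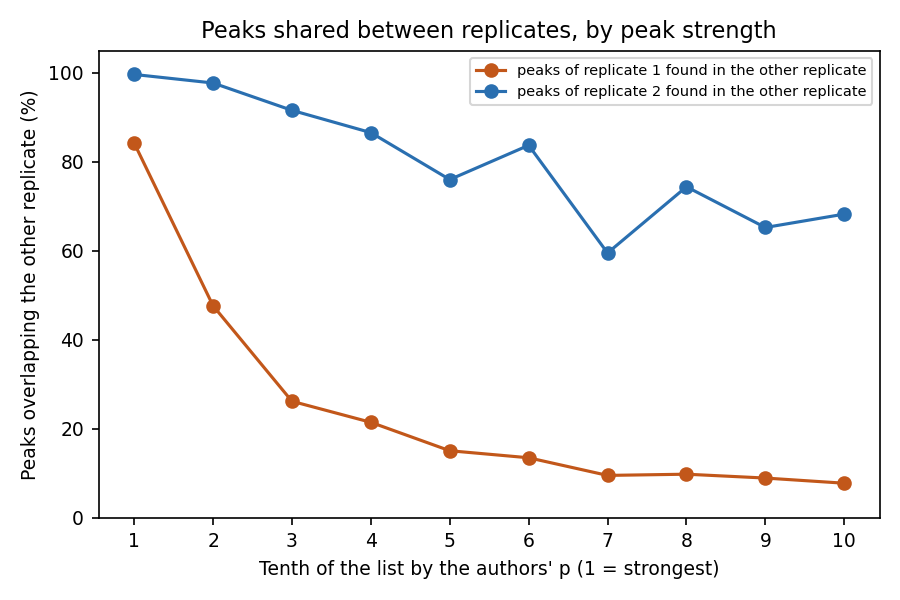
Percent of peaks that overlap a peak of the other replicate by at least 1 base (y axis), for 10 equal parts of a replicate's list ranked by the authors' p (x axis, 1 is the strongest), with replicate 1 in orange and replicate 2 in blue. The strongest parts stand at 84.2% and 99.7%, the weakest at 7.78% and 68.3%.

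All 35396 replicated peaks were identical intervals of the list of both replicates together, of which they made up 70.5%. Of them, 91.4% overlapped a replicate 1 peak and 54.2% a replicate 2 peak. Both replicate lists were overlapped by 49.6% (17550 peaks), which held 74.6% of the covered bases. Replicate 1 alone was overlapped by 41.8%, replicate 2 alone by 4.58% and neither by 4.05%. A replicated peak is therefore not in each case a peak found in both replicate lists. When only peaks found in both replicate lists were used, a setting chosen after seeing the data, 9 gene lists were again marked more often, with 12 of 27 cardiac transcription factors and all 39 Hox genes marked. The widest domain then spanned 189288 bases.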

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

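The peaks found in both replicates were chosen after seeing the data. All 9 gene lists marked more often kept their direction and their side of the threshold in each of 11 alternatives, from 2.77-fold to 13.7-fold, with adjusted exact p of at most 0.0149. The folds of the 10 named families and of the 4 genomic places kept theirs in every alternative run for them. No read depths were used, so which marked places were missed for lack of reads is open.

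The lists that changed direction had not passed the test. Cardiomyocyte contractile and conduction genes, at 0.852-fold, gave 1.01-fold to 1.31-fold over the single replicates, 1.05 with a 500-base window, 1.03 with a 2500-base window, 1.22 with 50% of the window covered and 1.08 with peaks found in both replicates. Smooth muscle genes gave 0.665 with a 500-base window and 0 with 50% covered, and 1.28 to 2.50 over the single replicates. Blood and immune genes, at 0.959-fold, gave 0.757 to 1.23 over the single replicates, 1.13 with peaks of both replicates together, 1.18 and 1.29 with windows of 500 and 2500 bases, 1.56 against CpG-matched sets and 1.11 with neighbours counted once. Liver, pancreas and gut genes gave 1.17 against CpG-matched sets, and Polycomb genes 1.55 with a 2500-base window. Germline genes, at 1.17-fold, gave 0.462 to 0.902 over the single replicates, 0.480 and 0.948 with windows of 500 and 2500 bases, 0.743 with 50% covered, 0.836 against CpG-matched sets, 0.828 with neighbours counted once, 0.538 with equal numbers of peaks and 0.495 with peaks found in both replicates. The cause was not tested.

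Skeletal muscle genes passed the threshold with 50% of the window covered (3.19-fold), and smooth muscle genes in replicate 1 alone. Housekeeping genes stayed at 0 in each setting, including 0 to 0 over the single replicates. They passed the threshold with peaks of both replicates together (adjusted exact p = 0.045), with a 2500-base window (0.027) and against CpG-matched sets (0.022), and the cause was not tested. The number of lists marked less often, 0, became 1 in those 3 settings and lay between 0 and 1 over the single replicates. Families marked less often numbered 7 to 12 over the single replicates.

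Domains numbered 9818 to 27572 over the single replicates and 6411 with peaks found in both replicates. Those of at least 10 kb numbered 572 to 1595, and 543 with peaks found in both, 473 with a gap of 1 kb and 1564 with a gap of 10 kb. Genes starting in them numbered 464 to 1075, and 442, 389 and 1172 in the same order. The widest domain spanned 148860 bases with a gap of 1 kb. A smaller gap splits domains by construction. The share of list members in domains of at least 10 kb was also recomputed for each replicate alone and with neighbours counted once, chosen after seeing the data. Of the 9 lists that passed there, neural crest and glial genes no longer did without replicate 1 (3.35-fold, adjusted exact p = 0.470), and the other 8 kept their calls. Lists without a call changed direction in 5 cases: contractile genes, at 0.986-fold, gave 1.08 with neighbours counted once; smooth muscle genes, at 2.50-fold, gave 0 without replicate 1; and Polycomb genes, at 1.48-fold, gave 0 over the single replicates and with neighbours counted once.

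The share of replicate 1 peaks found in replicate 2 was 14.7% under the stricter threshold, 14.3% with 50% of the peak covered and 43.9% with equal numbers. The share of replicate 2 peaks found in replicate 1 was 93.0%, 73.0% and 67.0%. The Jaccard index was 0.216 under the stricter threshold and 0.368 with equal numbers. The stricter threshold kept 52912 replicate 1 peaks and 10927 replicate 2 peaks, so its shares and index compare lists of unlike length. With 50% of the peak covered, 88.0% of replicated peaks were found in replicate 1 and 38.5% in replicate 2. No paired analysis was possible because there was one group.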

Other observations

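All 9 Pax, all 8 Lhx and all 8 metabotropic glutamate receptor (Grm) genes were marked, as were 11 of 14 serotonin receptor (Htr) genes (adjusted exact p = 3.1e-06, Fisher's exact test over 359 families), 7 of 8 Kcnh potassium channel genes and 9 of 12 Bmp genes (adjusted exact p = 6.2e-05). Collagen genes, many of them made by fibroblasts, were marked in 22 of 45 cases (3.46-fold, adjusted exact p = 9.5e-07), with 24 in replicate 1 and 16 in replicate 2. At the other end, 0 of 54 translation initiation factor (Eif) genes and 0 of 49 mitochondrial ribosomal (Mrpl) genes were marked (adjusted exact p = 0.0061 and 0.0082), in both replicates. Zinc finger genes with the Zfp symbol were marked in 25 of 394 cases (0.442-fold, adjusted exact p = 2.5e-05). Histone genes with the Hist symbol were marked in 1 of 67. These families were picked after their values were seen.

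Other wide domains held genes outside the fixed lists. The microRNA gene Mir9-1 started in a domain of 64491 bases on chromosome 3 (88192813 to 88257303), and the cell cycle inhibitor genes Cdkn2a and Cdkn2b in one of 44248 bases on chromosome 4 (89270341 to 89314588), with 74.1% of it covered in replicate 1 and 47.6% in replicate 2. Chromosome X had domains of 58236 bases at Tsix and Tsx (103393897 to 103452132) and of 46279 bases at Zfx (94121239 to 94167517), and 36.2% and 43.1% of them lay in replicated peaks. Of X-linked protein-coding genes 9.70% (92 of 948) were marked, against 14.4% of autosomal ones and 14.5% in autosomal sets matched on CpG content (p = 0.0002, permutation, two-sided, the smallest that 10000 sets can give). The sets drew single genes from all autosomes together, so this p treats neighbours as independent and does not measure the spread between chromosomes. Single autosomes ranged from 9.97% (chromosome 16) to 21.6% (chromosome 15) of genes marked in the replicated list. Replicate 1 marked 123 of 948, where matched sets gave 19.7%, and replicate 2 marked 8.12%, where they gave 12.0%. Replicated peaks on X were also weaker and narrower than autosomal ones (median −log10 p 4.84 against 5.47, median width 297 against 394 bases). Both replicates gave the same direction. The hearts were of mixed sex, and whether fewer X genes held the mark or fewer were detected was not tested. More than 5 kb from any protein-coding start, 5.66% of 4678 lincRNA starts and 5.03% of 1771 microRNA starts were marked, against 1.23% of 9153 processed pseudogenes. Replicate 1 alone gave 10.5%, 7.79% and 3.03%, and replicate 2 alone 4.57%, 4.23% and 0.885%. Coverage around Hox genes had medians of 9.01 kb of 10 kb for paralogues 1 to 4, 9.01 kb for 5 to 8 and 9.49 kb for 9 to 13. These groups do not compare places along the clusters, because each start is the outermost 5′ end of the gene record. That of Hoxa3 lay between those of Hoxa6 and Hoxa7, and Hoxd3 and Hoxd4 had the same coverage, 8.83 kb.

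Of the tests in the next 3 paragraphs, only the one on strong replicate 1 peaks within 3 kb was fixed before its result was seen. Replicate 1 had 2.43 times the peaks of replicate 2. For the strongest 10% of replicate 2 peaks, placement of the mark at different sites is argued against, since 99.7% overlapped replicate 1. The 6572 of 33344 replicate 2 peaks without such an overlap were weaker (median −log10 p 3.88 against 4.76), and for them the question stays open. Strong regions of replicate 1 alone are argued against too, since 97.3% of its strongest 10% had a replicate 2 peak within 3 kb, and only 215 of 8095 had none. Of all replicate 1 peaks 56.9% had one that near, and 84.2% of its strongest 10% overlapped replicate 2 directly. Weaker detection in replicate 2 stays open: sharing fell by 76.5 points from the strongest to the weakest 10% of replicate 1 peaks, but these also narrowed from a median of 982 to 209 bases, sharing of replicate 2 peaks fell too (99.7% to 68.3%), and spurious weak calls in replicate 1 would give the same fall. Depth, antibody yield and the further files behind each list were not tested, and the design gives no biological group to set against them.

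The replicated list held peaks not found in both replicates. A rule of overlap with both replicate lists is argued against, because 50.4% of the replicated peaks lacked it for at least one. A rule that accepts 50% overlap of either peak in both lists could account for part of the list, since 100% of the 17152 pooled peaks that met it were replicated. The other 18244 replicated peaks did not meet it, so a further way into the list is needed, and the files used here do not show it. Replicated peaks outside the overlap of both lists were weaker, with a median −log10 p of 4.47 against 7.09. No biological explanation was tested.

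In the endothelial, fibroblast and smooth muscle lists 23 of 49 genes were marked, and in the cardiomyocyte contractile and energy lists 5 of 48 (28 and 10 in replicate 1 alone, 19 and 5 in replicate 2 alone), a grouping made after the values of these lists were seen, so that its size tests nothing by itself; neural crest and glial genes (8 of 14) went with it and blood and immune genes (3 of 22) against it. Promoter CpG class, rich or poor, is argued against as the whole cause of the difference between these lists, with 11 of 12 against 3 of 9 CpG-rich and 12 of 37 against 2 of 39 CpG-poor members marked (common odds ratio 11.2, 95% interval 2.94 to 42.8). CpG content can still differ within a class. The ratio also includes transcription factors and lists picked after their values were seen, so its size is not an unbiased estimate. Transcription factors could account for part of the difference of 36.5 points. All 11 of the endothelial, fibroblast and smooth muscle lists were marked, while the 1 in the energy list, Esrra, was not. Without them the difference was 20.9 points in the replicated list (Fisher's exact p = 0.0274), 23.5 in replicate 1 (p = 0.0341) and 18.3 in replicate 2 (p = 0.0494), and with the coactivator Ppargc1a left out as well 20.7, 23.0 and 18.1 (p = 0.0281, 0.0346 and 0.0506). The sizes are alike, but the call in replicate 2 turns on 1 gene and the lists were picked after their values were seen, so whether the difference holds without transcription factors stays open. No biological explanation was tested.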
